A study of Mus musculus with 6 samples.

How the data were processed

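Small RNA was sequenced from 6 libraries of melan-alpha, an immortalised line of pigmented mouse melanocytes that the labels place under mouse skin. In 3 libraries the cells had been infected with a lentivirus carrying the mouse Mitf gene, and 3 libraries were controls. Cells were grown in RPMI medium with 10% fetal bovine serum, and libraries were made with the TruSeq small RNA kit, per the labels' protocols. The source label of every sample is extracellular vesicle, and the series describes vesicle microRNA profiles, whereas the extraction protocol in the labels describes collecting and washing cells. How vesicles were isolated is not given in the sources used here, so the values below are of libraries labelled as vesicle RNA. The labels do not say whether replicates came from separate cultures, and p-values measure only the spread between these samples, which may be technical. Per the submitters' processing notes the genome build was mm9. The aligner and counting tool are not given in the sources used here.

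The authors deposited a table with 1 row per sequence, holding estimated counts of reads for each library, which need not be whole because a read that matches several rows is split among them. Per the file headers, the same table holds normalized values, a signal that equals the estimated count divided by 1 factor per library. That relation was checked on the file, and the rule behind the factor is not given in the sources used here. The authors also deposited group means, a fold change as the ratio of those means, its log2, and an unadjusted p-value per row, per the file headers. A further deposited table holds the count of reads and of unique sequences in each read class, with the authors' percent of raw reads. Per the file headers, the classes run from adapter and length filtering to reads called valid. They are not separate, since a class named Rfam is made up of the rRNA, tRNA, snRNA, snoRNA and other Rfam classes. Leaving these parts aside, the shares still add up to more than all raw reads in each library, so some reads are counted in several classes. All per-sample columns of both tables were used. 4 lines of the microRNA table were empty and were not used here.

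Of the 1560 rows, 506 carried a mouse microRNA name, 837 a name for a predicted sequence, 93 a cow name and 124 the name of another mammal. A suffix in a row's name marks added or missing end bases or a substitution against the reference microRNA. 30 rows shared their sequence with an earlier row, so reads could be split between them, and 708 rows were above 0 in only 1 library. Rows of near-identical family members, such as the let-7 microRNAs, are uncertain for the same reason.

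The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter at its default minimum count of 10, and the quasi-likelihood test, on all 6 libraries with group as the only term. The design fixed in advance had expected either whole counts or normalized values alone, and the rounded estimated counts took the place of whole counts. P-values were adjusted by Benjamini-Hochberg over the tested rows, with a threshold of 0.05. Levels are CPM, read counts scaled to a common library total with the TMM factors, and log2 fold changes are MITF overexpression minus control with their standard errors. A row is called not overlapping when all libraries of one group lie above all libraries of the other.

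20 lists of microRNAs (families, genomic clusters, microRNAs tied to MITF or pigmentation, and markers of other cell types and of blood) were fixed before the data were examined, together with the design and the rule for naming rows. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists. Camera tests a list against the other rows. Camera with an estimated correlation and the fry test, which tests a list against no change, were alternatives. Rows whose sequence holds GGAG or CCCT, motifs reported for vesicle export, were tested in the same way. Shares of read classes were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1. The naming rule took the 10 largest rises and 10 largest falls past the threshold with groups that did not overlap and a scaled mean of at least 50 in either group, the 10 most abundant rows, up to 4 abundant and up to 4 called members of each list, and miR-211, miR-204, miR-137, miR-148a, miR-182 and miR-21a. Predicted sequences were counted and not named. Rows named outside this rule are said to have been chosen after their values were seen.

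Positions come from an exact match of each mature sequence to the microRNA transcripts of GENCODE M21, on GRCm38. This is not the authors' build, and no coordinates were converted. Cow-named rows were compared with mouse transcripts only, since no cow sequence and no mouse genome sequence was used here.

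Tabulated reads per library ran from 279142 to 475977, and 3 reads, the limit that a count of 0 allows, correspond to 6.30 to 10.7 CPM of the tabulated reads. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed by more than sampling noise, with a chi-square of 21.2 to 64.2 per degree of freedom over the 6 pairs. The test was run on simulated data made from the real means, library sizes and dispersions of all 1560 rows, with 200 rows changed. In 421 rows that passed the filter, 42.2% of the rows changed by a fold of 2 and 87.9% of those changed by a fold of 4 were recovered for this comparison, and 1 of 240 unchanged rows was called. Alternatives were DESeq2 1.42.0, other scalings, other filters, other choices of rows, leaving out each library in turn and a replicate block.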

Results

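MicroRNAs were profiled in 3 libraries from melan-alpha melanocytes infected with a lentivirus carrying Mitf and in 3 control libraries, all labelled as extracellular vesicle RNA. MITF is the transcription factor that drives the pigment cell program, including the genes of melanin synthesis. The question set by the design was which vesicle microRNAs differ when MITF is overexpressed. The Mitf transcript is not measured by this assay, so the overexpression itself was not checked here. The control libraries held 342941, 382350 and 475977 tabulated reads, and the MITF overexpression libraries held 448969, 279142 and 306062. The most abundant row in every library was a predicted sequence, which took 8.02%, 15.6% and 16.1% of reads in the controls and 16.4%, 20.7% and 19.7% with MITF overexpression.

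MiR-211-5p, encoded inside the melanocyte gene Trpm1, a known target of MITF, was 2.14-fold higher with MITF overexpression, at 4591 ± 548 CPM against 2142 ± 431 CPM in controls (SD, n = 3). The opposite arm of the same precursor, miR-211-3p, was 4.90-fold higher. MiR-21a-5p, one of the most abundant microRNAs of many cultured cells, was 3.20-fold lower, at 14812 ± 2366 CPM against 47404 ± 14152 CPM. By camera with a preset correlation, the list of blood cell and serum markers was higher, with 5 of 9 members past the test, as was that of the imprinted Dlk1-Dio3 cluster, with 6 of 14, and the list of the miR-17-92 cluster and its paralogs was lower, with 3 of 13. All 3 list calls were lost with an estimated correlation, at an adjusted p of 0.583 for each. That shared value comes from the adjustment over lists. Before it, camera gave a p of 0.146 for the blood list, 0.0426 for Dlk1-Dio3 and 0.216 for miR-17-92. The estimated correlations were 0.538, 0.0295 and 0.310. Over all 441 tested rows, 44 were higher and 23 lower past an adjusted p of 0.05 by edgeR's quasi-likelihood test, and 374 were not called. The groups did not overlap in 42.4% of tested rows, where chance gives 10%.

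**Figure D1:**
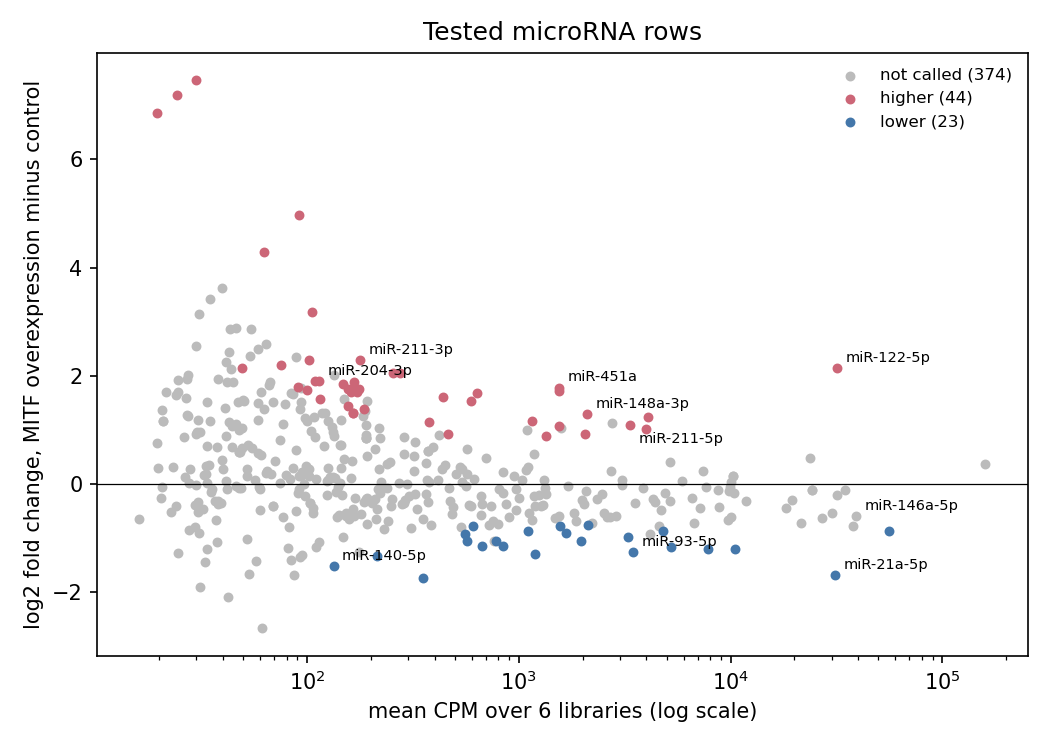
Each point is 1 of the 441 tested rows, with its mean CPM over 6 libraries on a log axis and its log2 fold change, MITF overexpression minus control. The 44 rows called higher are red and the 23 called lower are blue, and the 3 red points with the greatest log2 fold change had no control reads, so their fitted values depend on the prior count.

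Of the 285 tested rows with a mouse name, 22 were higher and 15 lower. Of 96 predicted rows, 9 were higher and 6 lower. Of 32 rows with a cow name, 8 were higher and 2 lower, and of 28 rows named after other mammals 5 were higher and none lower. The counts depended on single libraries, since 0 rows passed edgeR's test without MITF overexpression replicate 3, where 135 had an unadjusted p under 0.05 and the lowest adjusted p was 0.069. Without control replicate 2 there were 7 higher and 4 lower rows, without MITF overexpression replicate 2 there were 11 and 3, and without control replicate 3 there were 41 and 8. The share of calls that were higher was 65.7%. It was 80.5% with total-count scaling, with 62 higher and 15 lower rows and a shift of 0.16 in the median log2 fold change, and 54.3% when the most abundant row was left out before scaling, with 44 higher and 37 lower rows.

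The precursor of miR-211 lies at chromosome 7, 64205806 to 64205911 on the plus strand of GRCm38, in an intron of Trpm1. The log2 fold change of miR-211-5p was 1.10 ± 0.22 (SE), with an adjusted p of 0.0211 by edgeR. MiR-211-3p stood at 296 ± 130 CPM against 59.7 ± 12.9 CPM, with an adjusted p of 0.0200. MiR-204, whose seed is the same as that of miR-211, is encoded in an intron of Trpm3 at chromosome 19, 22750605 to 22750672. Its 3p arm rose from 47.8 ± 7.59 to 180 ± 76.9 CPM, with an adjusted p of 0.0221. A row named after its 5p arm had 5, 9 and 0 reads with MITF overexpression and 0 in each control library and was not tested. The name of that row marks a substitution of A by T at base 17 of miR-204-5p, so it need not measure that arm. In the authors' deposited table the fold change of miR-211-5p was 2.19 and its unadjusted p was 0.00248.

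Among 9 tested members of the list of microRNAs reported to repress Mitf, 1 rose and 2 fell, with 1 higher and 3 lower adjusted over the list alone. MiR-148a-3p rose 2.46-fold to 2995 ± 652 CPM from 1218 ± 236 CPM, with an adjusted p of 0.0200. MiR-101b-3p fell 2.08-fold and miR-340-5p fell 2.22-fold, with adjusted p of 0.0348 and 0.0410. MiR-25-3p and miR-148b-3p had log2 fold changes of -0.66 and -0.54 and did not pass, with adjusted p of 0.0568 and 0.155. The list as a whole did not pass, with an adjusted p of 0.119 by camera. With 1 library left out, its adjusted p ran from 0.0470 without MITF overexpression replicate 1 to 0.2585 without MITF overexpression replicate 2. It was 0.583 with an estimated correlation. No mouse-named row of miR-137 was listed among the deposited rows, and miR-182-5p had 16 reads in MITF overexpression replicate 1 and 0 in the other 5 libraries.

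Of 8 tested members of the list near or bound by MITF, 2 rose, both from miR-211, and the adjusted p of the list was 0.840. Adjusted over the list alone, 2 were higher and 2 lower. MiR-146a-5p and miR-221-3p did not pass, with log2 fold changes of -0.59 and -0.61. Of 13 members of the pigmentation list, 4 rose and 1 fell, with 6 higher and 3 lower adjusted over the list alone, and the adjusted p of the list was 0.714. Those that rose were both arms of miR-211, miR-204-3p and miR-145a-5p, and the one that fell was miR-21a-5p. MiR-145a-5p, a microRNA of smooth muscle and fibroblasts, stood at 264 ± 96.7 CPM against 69.8 ± 44.4 CPM with an adjusted p of 0.0416.

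**Figure D2:**
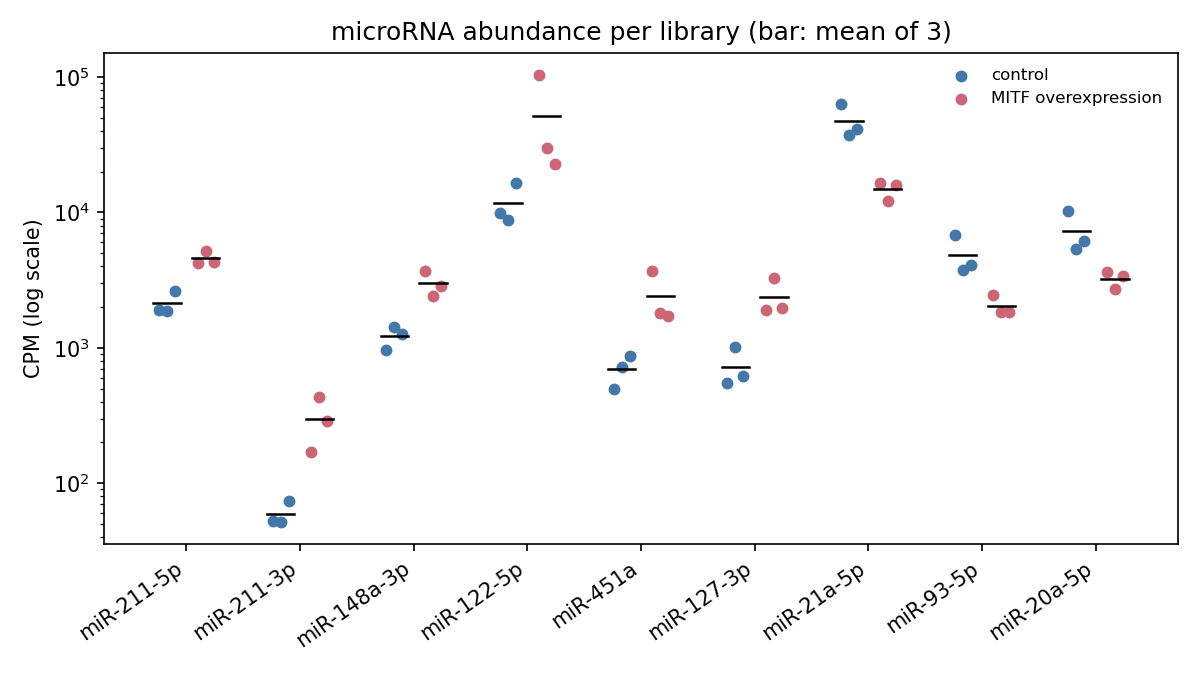
Each point is 1 library's CPM on a log axis, for 9 microRNAs with control libraries in blue and MITF overexpression libraries in red, and each bar is the mean of 3. MiR-211-5p lies between 1880 and 2640 CPM in controls and between 4220 and 5220 CPM with MITF overexpression, and miR-122-5p reaches 102960 CPM in replicate 1 of the latter.

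In the list of blood cell and serum markers, 5 of 9 tested members rose and none fell, and 8 were higher adjusted over the list alone. Members are rows and not separate microRNAs, since they include both arms of miR-144 and a further row from the miR-451a precursor. MiR-451a and miR-144-3p, which are processed from one transcript in red blood cells, rose 3.44-fold and 3.23-fold. MiR-486b-5p rose 2.23-fold, and miR-142a-5p, a microRNA of white blood cells, rose 2.88-fold. MiR-122-5p, the main microRNA of liver, stood at 51936 ± 44342 CPM against 11713 ± 4080 CPM. Its level was 102960 CPM in MITF overexpression replicate 1 against 30121 and 22727 CPM in replicates 2 and 3, and without replicate 1 its log2 fold change went from 2.15 to 1.15 with an adjusted p of 0.0396. The median log2 fold change of the list was 1.69, with an adjusted p of 0.00148 by camera. The call was lost with an estimated correlation, where the adjusted p was 0.583. Camera compares a list with the other rows, and fry, which asks whether a list changed at all, gave an adjusted p of 0.0532.

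In the Dlk1-Dio3 cluster, an imprinted domain of chromosome 12 with many microRNA genes, 6 of 14 tested members rose and none fell, and 9 were higher adjusted over the list alone. MiR-127-3p, at chromosome 12, 109592846 to 109592915, rose 3.29-fold from 723 ± 248 to 2385 ± 790 CPM. MiR-369-3p rose 2.03-fold, miR-495-3p 3.47-fold, miR-136-3p 2.62-fold and miR-494-3p 1.90-fold. MiR-409-3p had 43, 43 and 38 reads with MITF overexpression against 6, 0 and 0 in controls, with an adjusted p of 0.0236. The median log2 fold change of the list was 1.31, with an adjusted p of 0.0110 by camera, 0.583 with an estimated correlation and 0.0223 by fry. Without MITF overexpression replicate 3 the adjusted p of the list was 0.0694.

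In the miR-17-92 cluster and its paralogs, which are tied to cell growth, 3 of 13 tested members fell and none rose, and 5 were lower adjusted over the list alone. The log2 fold change was positive in 3 of the 13. MiR-93-5p, encoded with miR-106b in the gene Mcm7 on chromosome 5, fell 2.39-fold to 2045 ± 355 CPM. MiR-106b-3p fell 1.86-fold, and miR-20a-5p, encoded in the Mir17hg transcript on chromosome 14, fell 2.23-fold. MiR-17-5p had a log2 fold change of -0.78 with an adjusted p of 0.0679, and miR-92a-3p one of -0.06 with an adjusted p of 0.872. The adjusted p of the list was 0.0173 by camera, 0.583 with an estimated correlation and 0.114 by fry. It was 0.174 without control replicate 1, 0.0666 without MITF overexpression replicate 2, 0.201 without replicate 3 and 0.0568 among mouse-named rows alone.

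MiR-21a-5p, at chromosome 11, 86584067 to 86584158 on the minus strand in an exon of Vmp1, had a log2 fold change of -1.68 ± 0.26 (SE) with an adjusted p of 0.0189. In the authors' deposited table its fold change was 0.320 and its unadjusted p 0.0582. MiR-140-5p, encoded within Wwp2, fell 2.87-fold to 68.5 ± 10.1 CPM. MiR-34c-5p, a target of p53, fell 1.70-fold, miR-152-3p fell 1.83-fold and miR-322-3p fell 1.71-fold. The list of melanoma-associated microRNAs had 2 members that rose and 1 that fell among 12, with the same counts adjusted over the list alone, and an adjusted p of 0.457. MiR-214-3p rose 3.36-fold. MiR-199a-5p, whose sequence matches precursors on chromosomes 1 and 9, stood at 190 ± 231 CPM against 20.8 ± 9.41 CPM, and without MITF overexpression replicate 1, which held 200 of its reads against 19 and 17 in the others, its adjusted p was 0.355.

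Among the most abundant mouse microRNAs, miR-21a-5p and miR-122-5p passed the test, as given above, and the following did not. MiR-146a-5p stood at 31373 ± 5257 CPM against 47122 ± 6252 CPM, with an adjusted p of 0.0805. MiR-30a-5p and miR-30d-5p had log2 fold changes of -0.79 and -0.63, with adjusted p of 0.0580 and 0.0910. Let-7b-5p and let-7i-5p had log2 fold changes of -0.12 and -0.21, and let-7g-5p one of -0.53 with an adjusted p of 0.0812. None of the 17 let-7 rows, 11 miR-30 rows, 9 miR-23/27/24 rows, 8 miR-99/100 and miR-125 rows or 4 miR-181 rows passed. The adjusted p of these lists was 0.211, 0.160, 0.142, 0.840 and 0.199.

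The remaining family lists did not pass either, with adjusted p of 0.516 for the miR-29 family, 0.454 for the family of miR-15 and miR-16 and 0.126 for the miR-34 family. Among markers of other cell types, 3 of 10 fibroblast and mesenchymal members rose and 1 fell, with 4 higher and 1 lower adjusted over the list alone, and the adjusted p was 0.359. None of the 10 endothelial, muscle and neural members passed, and the adjusted p of that list was 0.119. MiR-126a-3p, an endothelial microRNA, was at 7771 CPM in MITF overexpression replicate 1 and between 1540 and 2084 CPM in the other 5 libraries. The keratinocyte list had 2 tested members, miR-200b-3p and miR-205-5p, and neither passed, with adjusted p of 0.620 and 0.859. No member of the miR-183 or Sfmbt2 cluster was tested.

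Some of the largest changes were in rows that are not standard mouse microRNAs. A variant of mir-5112 had 48, 107 and 21 reads with MITF overexpression against 0, 6 and 0 in controls, with an adjusted p of 0.0215. Variants named after human miR-1246 and miR-7977 rose 4.16-fold and 3.75-fold, and cow-named miR-154c rose 4.89-fold. A variant of mir-6240 fell 2.31-fold to 6329 ± 2544 CPM, and a variant of cow-named miR-11987 fell 2.30-fold to 4734 ± 1473 CPM. The mir-5112 and mir-6240 variants matched no mouse transcript.

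**Figure D3:**
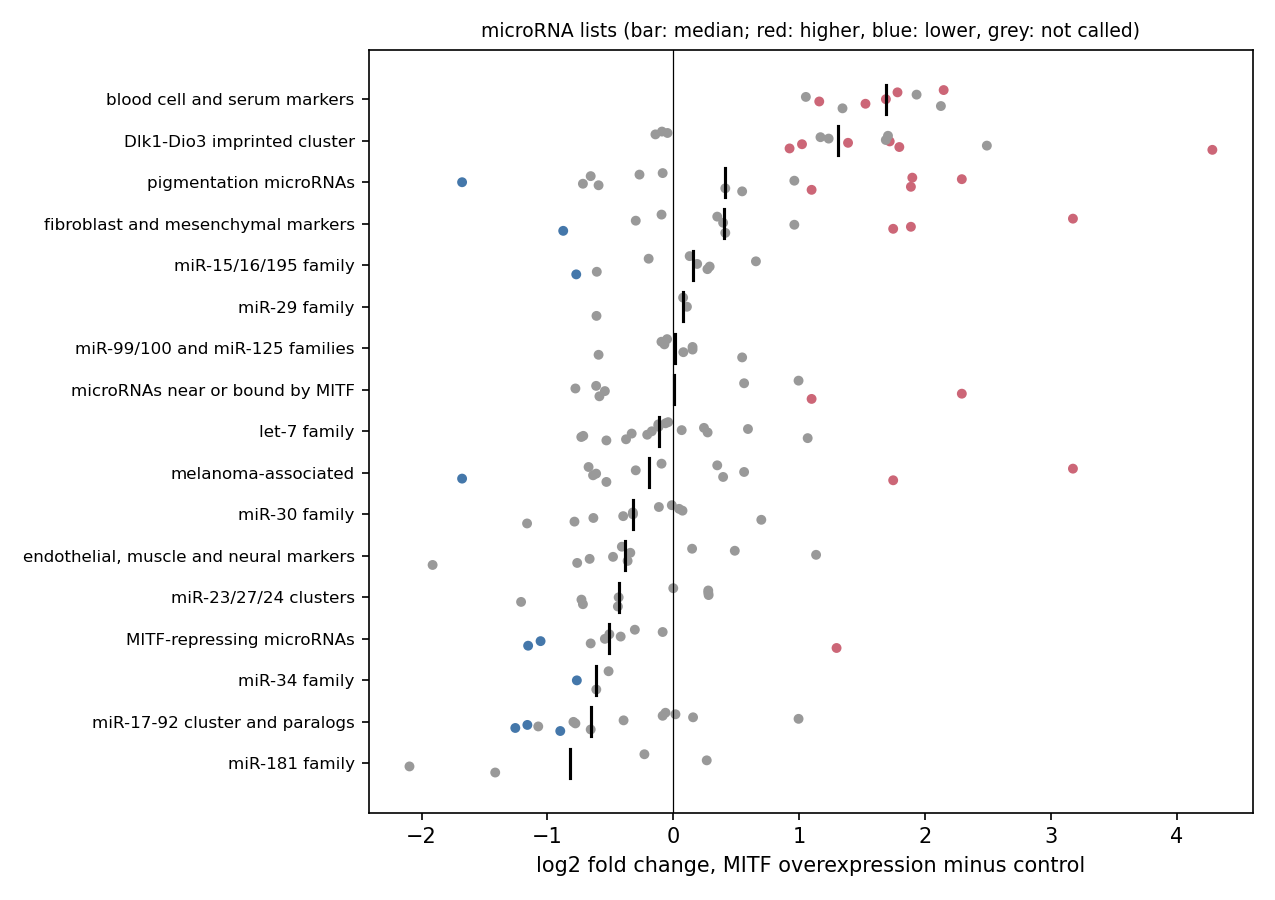
Each point is the log2 fold change, MITF overexpression minus control, of 1 tested member of 1 of 17 lists, and each bar is the list's median. Members called higher are red, those called lower are blue, and the list medians run from -0.82 for the miR-181 family to 1.69 for blood cell and serum markers.

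Rows holding the GGAG or CCCT motif numbered 100 against 341 without it, with a median log2 fold change of 0.19 against 0.05. The difference of 0.15 did not pass the threshold of 0.05 by camera. Among mouse-named rows alone it was 0.27 and passed at the preset correlation, a call lost with an estimated correlation, where camera gave a p of 0.355. Without control replicate 3 the difference was -0.08.

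Read classes were compared as shares of raw reads, of which there were 10030115 to 16275268 per library. Reads matching mRNA made up 4.37 ± 0.24% with MITF overexpression and 3.04 ± 0.80% in controls, and repeats 0.519 ± 0.047% and 0.427 ± 0.041% (SD, n = 3). Ribosomal RNA made up 6.03 ± 0.43% and 7.20 ± 0.48% of reads, but its direction turned when unique sequences were counted in place of reads, at 1.25 ± 0.21% and 0.847 ± 0.103%. In these 3 of 11 classes, some of which share reads, the groups did not overlap. The exact permutation p was 0.1, the smallest that 3 against 3 allows. Transfer RNA fragments made up 5.02 ± 0.47% and 3.71 ± 1.02%, and reads called valid 56.7 ± 4.5% and 60.7 ± 1.4%, and these groups overlapped. As shares of the reads left after adapter and length filtering, the groups did not overlap for either class, at 6.79 ± 0.38% and 4.85 ± 1.08% for transfer RNA and 76.7 ± 0.97% and 79.9 ± 2.3% for valid reads.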

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

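The tests of scaling, serum RNA and liver-derived reads and the count over splits were written down after the results they bear on had been seen, while the camera list tests, their estimated-correlation and fry alternatives and the leaving out of libraries were planned. Among 1119 rows too low to be tested, 27 were above 0 in every MITF overexpression library and in no control library, against 4 the other way round. They stood out as signal outside the tested rows with a count of 0 in each control, and held 5.67 to 66 reads per row over the 3 libraries. 14 were predicted sequences, 7 had mouse names, 5 had cow names and 1 was named after another mammal. More rows of any kind were above 0 with MITF overexpression, at 992, 860 and 783, than in controls, at 513, 612 and 677. The excess is therefore not particular to these rows.

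The real split of the 6 libraries gave 67 calls and the highest of the other splits gave 0, so 1 of 10 splits gave as many. With 10 splits the share cannot fall below 0.1, which is too few to decide.

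The blood cell and serum list was higher with MITF overexpression by camera at a preset correlation, a call lost with an estimated correlation (adjusted p = 0.583). The choice among the 6 scalings tried does not account for the rise, since the lowest median log2 fold change of the list was 1.64. The largest shift among them was 0.16 in the median log2 fold change, with total-count scaling, so a larger scaling error was not tested. Only the single most abundant row was left out, so the weight of a few abundant rows was not tested either. A candidate explanation is more RNA from the serum of the culture medium, and its tests disagreed. Cow-named rows without a match among mouse transcripts were set against mouse-named rows outside the blood and Dlk1-Dio3 lists. Their median log2 fold change was 1.195 higher (two-sided permutation p = 2e-05). The permutation shuffled rows, some of them variants of one microRNA, so its p does not measure the spread between libraries. The summed abundance of these cow-named rows was 0.692 times that of controls, at 16119 ± 3281 against 23299 ± 7401 CPM, and the groups overlapped. Rows without a cow name rose too, with medians of 0.69 for predicted rows and 0.70 for other mammals against -0.07 for all mouse-named rows. However, 93 of 96 predicted rows and 22 of 28 rows of other mammals matched no mouse transcript either, so their origin is also open. The sum is ruled by 10 rows that carry a substitution against the cow sequence, at 10256 ± 3263 CPM against 20704 ± 7471 CPM. Among these, the variant of cow-named miR-11987 given above alone stood at 4734 ± 1473 CPM against 10886 ± 2857 CPM, so the fall of the sum rests largely on that row. The 21 rows without a substitution stood at 5863 ± 61.4 CPM against 2595 ± 253 CPM. Without a cow or mouse genome it stays open which of these rows come from cow. An effect of MITF on these microRNAs stays open too and was not tested.

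MiR-122-5p was highest in MITF overexpression replicate 1. More serum RNA in that library is argued against so far as cow-named rows measure it, since their sum there was 1.19 times the mean of replicates 2 and 3, and 0.988 and 1.32 times for the rows without and with a substitution. Liver-derived reads in that library may account for the pattern, since the liver microRNAs miR-192-5p and miR-194-5p were 3.60 and 5.07 times the mean of replicates 2 and 3. MiR-126a-3p and miR-199a-5p, which are on the endothelial and fibroblast lists, were 4.29 and 8.01 times their means in replicates 2 and 3. The red blood cell microRNA miR-451a was 2.09 times its mean, and miR-211-5p and miR-21a-5p were 0.884 and 1.17 times theirs. The excess is therefore wider than the liver markers. This does not argue against liver tissue, which also holds endothelial and blood cells, and a liver source stays unproven. No biological explanation was tested, since the labels give this library no difference from the other replicates.

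The Dlk1-Dio3 list was higher with MITF overexpression by camera at a preset correlation, a call lost with an estimated correlation (adjusted p = 0.583) and without MITF overexpression replicate 3 (adjusted p = 0.0694). Liver-derived reads in replicate 1 are argued against as the whole cause, since the median log2 fold change of the list was 0.998 without that library. Serum RNA could be a source, since the 3 cow-named rows of the cluster had a median log2 fold change of 2.29 and 2 of them passed. These 3 rows carry no substitution, and the sum of cow-named rows without one was higher, as given above. The sum of all cow-named rows was not higher, with groups that overlapped, so this stays open. An effect of MITF stays open and was not tested.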

How the results depend on the processing

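Settings that leave out the most abundant row, restrict rows to mouse names outside the blood and Dlk1-Dio3 lists, use the authors' factors or use limma on the deposited normalized values were chosen after seeing the data; the rest were planned. None of the 67 calls changed direction under any setting in which it was tested. The groups of all 67 did not overlap, so leaving out a library could hardly reverse a call, and the kept direction is no sign of stability. The cause of the changes below was not tested unless fewer libraries or rows entered the fit. The pseudocount alternative was not run, since counts were tested. Against 44 higher and 23 lower, DESeq2 gave 67 and 43, the filter at a scaled mean of 100 gave 25 and 10, mouse-named rows gave 26 and 23, and mouse-named rows outside both lists gave 8 and 6. Total-count scaling gave 15 lower and leaving out the most abundant row 37 lower. Leaving out 1 library gave 0 to 41 higher and 0 to 23 lower. The labels give the groups the same replicate numbers. The deviations of same-numbered libraries correlated at -0.0477, 0.0418 and -0.0145, and not every library correlated best with its own number. These deviations showed no pairing, which does not exclude that same-numbered libraries were handled together. In both groups replicates 2 and 3 differed least, with a chi-square of 21.2 and 24.6 per degree of freedom. With a replicate block 1 row was higher and 1 lower. Of 84 rows that met the naming rule, which include 6 predicted sequences that are not named, 39 were called, 5 of them predicted, and 37 of the 39 lost the call under the block and 2 with limma; without control replicates 1, 2 and 3 in turn 9, 28 and 12 lost it, and without MITF overexpression replicates 1, 2 and 3 in turn 7, 30 and 39.

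Against 3 lists past the threshold, 12 passed with no filter, 0 with an estimated correlation (camera), 1 with fry, which tests a list against no change and not against the other rows, and 1 to 5 when 1 library was left out. For the EXOmotif list, rows with GGAG or CCCT, the difference of 0.147 was 0.273 among mouse-named rows, where it passed at the preset correlation and not with an estimated one (p 0.355, added after seeing the data), and ran from -0.0754 to 0.300 when 1 library was left out, reversing without control replicate 3. Against 3 read classes without overlap there were 5 as shares of reads left after filtering, where transfer RNA and valid reads were added, 8 by unique sequences, where ribosomal RNA turned from lower to higher, 8 with 3 same-number differences of one sign under the replicate block, and 3 to 6 when 1 library was left out. Some of these classes share reads, so these counts are not of separate classes. The depth of 279142 to 475977 reads limits rows below about 3 reads per library.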

Other observations

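Rows named in this part were chosen after their values were seen. MiR-22-3p rose from 2427 to 5704 CPM, with an adjusted p of 0.0446 by edgeR, while its opposite arm miR-22-5p had a log2 fold change of -0.22 and an adjusted p of 0.617. MiR-335-5p, encoded in an imprinted gene, rose from 1415 to 2694 CPM, with an adjusted p of 0.0211. A row named after miR-709 rose from 235 to 522 CPM, with an adjusted p of 0.0469, but its sequence matches transcripts of 78 mouse genes, so it need not measure that microRNA. MiR-28a-3p, miR-421-3p, miR-744-5p and miR-532-5p fell, with log2 fold changes of -1.06, -0.93, -0.86 and -0.77.

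More rows were above 0 in the MITF overexpression libraries, at 992, 860 and 783, than in the controls, at 513, 612 and 677, although the controls were not sequenced less deeply as a group. Tabulated reads made up 5.17 ± 0.40% of valid reads with MITF overexpression and 4.58 ± 0.10% in controls (SD, n = 3), an exact permutation p of 0.1. The authors' deposited table gives 109 rows with an unadjusted p under 0.05, 75 higher and 34 lower, and 42 of the 67 rows called here were among them.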
